A study of Mus musculus with 16 samples.

How the data were processed

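The series measured RNA of neutrophils taken from mouse lungs 24 h after an intratracheal dose of Streptococcus pneumoniae (SP) or of phosphate-buffered saline (PBS) alone. Mice were wild type (WT) or Nrf2 null, where Nrf2 is another name of Nfe2l2, the gene for the transcription factor NRF2. Neutrophils were taken with magnetic beads against Ly6G, a surface protein of mouse neutrophils, and their RNA was hybridised to Affymetrix Mouse Gene 2.1 ST arrays. The 16 arrays form 4 groups of 4: WT_PBS, WT_SP, Nrf2null_PBS and Nrf2null_SP. Arrays are named by group and by the replicate number in the labels.

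The authors made the deposited values as log2 RMA intensities, in which background correction, quantile normalization and summarization of probes give 1 value per probe set. Affymetrix Expression Console and Partek are named beside RMA, and their versions, their roles, the probe set definition and the genome build are not given in the sources used here. The values were used as deposited, with no further normalization and no filter on dim probe sets. Of 31351 probe sets, 21059 had a transcript accession with 1 gene symbol in the RefSeq gene table for the mouse assembly GRCm38.p6, and 10292 had none and were left out. Where a gene had several probe sets (35 genes), the probe set with the highest mean over the 16 arrays stood for it, which left 21024 genes. Genes with no named probe set, such as Ly6g, were not analysed here.

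A linear model with 1 mean per group was fitted to all 16 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3, 12 residual and 2.68 prior degrees of freedom). The 5 contrasts were SP against PBS in WT, SP against PBS in Nrf2 null, Nrf2 null against WT after PBS, Nrf2 null against WT after SP, and the difference of the SP responses (Nrf2 null minus WT). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the 21024 genes of a contrast. All tests were 2-sided unless named otherwise. Errors of changes are standard errors (SE) from limma, and errors of group levels are standard deviations (SD, n = 4). The number of arrays limits the precision, and the median SE of a log2 change was 0.132, or 0.187 for the difference of the responses.

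Gene lists for 22 pathways and 13 cell types were tested with limma's camera, at a preset inter-gene correlation of 0.01, with adjustment over 35 lists in each contrast. The pathway lists were NRF2 target genes, other antioxidant enzymes, NADPH oxidase, glycolysis, oxidative phosphorylation, primary granule proteins, secondary and tertiary granule proteins, proinflammatory cytokines, chemokines, NF-kappaB feedback and target genes, type I interferon response, interferon gamma response, pattern recognition receptors, migration and adhesion receptors, apoptosis regulators, hypoxia response, endoplasmic reticulum stress, cell cycle, lipid mediator synthesis, metal handling, complement and scavenger receptors, and cholesterol and fatty acid synthesis. The marker lists covered neutrophils, alveolar macrophages, monocytes and interstitial macrophages, dendritic cells with MHC class II, T and NK cells, B cells, epithelium, endothelium, fibroblasts with smooth muscle, erythroid cells, platelets, mast cells with basophils and eosinophils, and neutrophil precursors. Sex-linked genes were read as values only. Some genes stand in more than 1 list. Groups, contrasts, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined.

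The rule for named genes took Nfe2l2 first. In each contrast it then took the 10 largest rises and the 10 largest falls among called genes whose 4 arrays of one group did not overlap the 4 of the other, without predicted genes, small RNA genes and immunoglobulin or T cell receptor segments. Up to 4 called members with the largest changes were taken per list, or up to 2 members as values where none was called. For contrasts with fewer than 10 calls, the 5 genes with the smallest p were added. In the comparison after PBS, Creg1, Gclm, Gsta3 and Slc22a4 stand beside their values after SP, a choice made after their values were seen.

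Alternatives covered the choice of probe set, all probe sets, a filter on dim probe sets, quantile normalization, centring of array medians over the 21024 genes, an intensity trend with a robust prior (statmod 1.5.0), no variance moderation, array weights, a fit of the compared groups alone, the replicate number as a block, a covariate for RNA of other cells and the omission of each array in turn. The covariate was the mean gene-centred value of 8 marker lists of other lung cells. The fit of the 13 arrays left after 3 PBS arrays that stood apart, and a batch term for those 3 arrays, were chosen after seeing the data. List tests were repeated with an estimated correlation and with fry. The method was tested on simulated data with known changes in 200 of 21024 genes per contrast, in which 70.1% to 85.1% of the genes changed by 1 log2 unit were recovered, with 7 to 16 false calls. Of the genes changed by 0.5 log2 units, 17.9% to 44.8% were recovered. Noise was drawn independently for each gene, without the structure shared by arrays here, so the false calls may not carry over to these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.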

Results

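RNA levels of lung neutrophils were measured on 16 arrays in a design of genotype by inoculation. WT and Nrf2 null mice received SP or PBS, with 4 arrays in each of the 4 groups. NRF2, the protein that Nfe2l2 encodes, is a transcription factor that drives genes of antioxidant defence and detoxification. The labels do not state that replicates are separate animals, so p-values here measure the spread between these samples. Array medians of all probe sets lay between 4.58 and 4.66 on the log2 scale, and no pair of arrays was identical. The lowest correlation across probe sets between 2 arrays of the same group was 0.973. In the list of sex-linked genes, Xist lay between 11.1 and 11.5 in every array and the Y-linked genes between 3.3 and 4.08. The median of the Y-linked genes, 3.61, is taken here as the level of a probe set with little or no target. A fold in which the lower group had a mean at or under 4.08 is given as a lower bound.

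Arrays separated by inoculation along the first principal component, which held 69% of the variance. The second component, with 10.9%, set 3 PBS arrays apart from the other PBS arrays: WT_PBS replicate 3 at 13.6, Nrf2null_PBS replicate 1 at 34.8 and Nrf2null_PBS replicate 3 at 29.9. The other PBS arrays lay between -24.6 and -19.4. Nrf2null_SP replicate 4 lay at -34.8, apart from the other SP arrays. Its mean over markers of other lung cells was -0.63, the lowest of the 16 arrays.

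**Figure D1:**
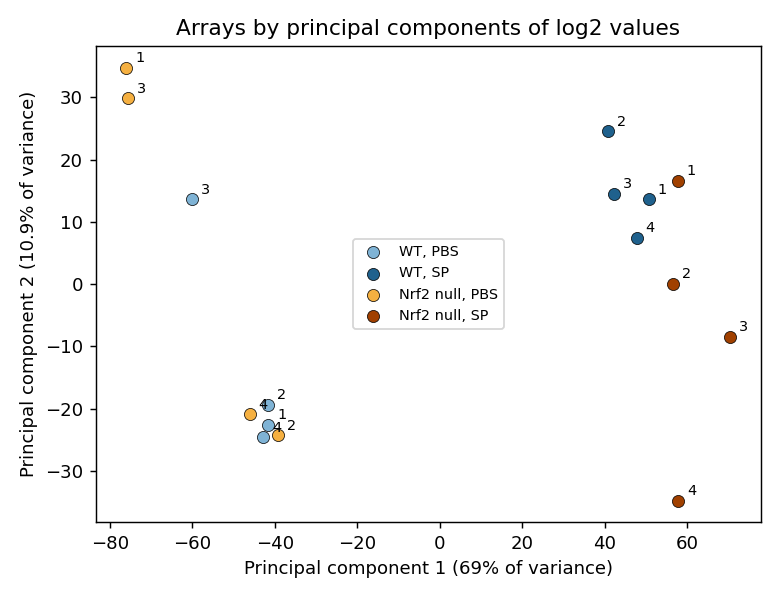
Each point is 1 of the 16 arrays, placed by its scores on the first principal component (x axis, 69% of the variance) and the second (y axis, 10.9%) of the log2 values of 21024 genes. SP arrays lie to the right and PBS arrays to the left, and WT_PBS replicate 3, Nrf2null_PBS replicate 1 and Nrf2null_PBS replicate 3 lie above the other PBS arrays.

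Nfe2l2 itself was measured at 11.37 ± 0.16 (SD, n = 4) in WT_PBS, 11.79 ± 0.06 in WT_SP, 11.23 ± 0.10 in Nrf2null_PBS and 11.48 ± 0.03 in Nrf2null_SP. The part of the gene that the null allele lacks and the positions of the probes are not given in the sources used here, so this is a weak check of the genotype. Nqo1, an NADPH quinone reductase and a classic NRF2 target, lay between 6.59 and 7.79 in the WT_PBS arrays and between 4.96 and 5.64 in the Nrf2null_PBS arrays.

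The first comparison asked which genes SP changed in WT neutrophils. SP raised interferon gamma response genes as a group. Type I interferon, chemokine, cytokine and apoptosis regulator genes also rose by camera, calls that did not hold with an estimated correlation (adjusted p between 0.0795 and 0.0987). Cxcl9, a chemokine that attracts activated T cells, rose 65.7-fold (log2 change 6.04, SE 0.275, n = 4 and 4, adjusted p = 7.90e-10). Gbp5, an interferon-induced GTPase, rose 39.2-fold (SE 0.111 on the log2 scale, adjusted p = 3.31e-13). Saa3, an acute phase protein, rose 44.4-fold and Hamp, which encodes the iron regulator hepcidin, rose at least 41-fold. The largest falls included Kcnj13, a potassium channel (14.7-fold, adjusted p = 1.90e-06), and Hba-a2, a globin of red cells (12.8-fold, adjusted p = 1.87e-04).

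In WT, 5852 of the 21024 genes (27.8%) were called, with 2815 higher and 3037 lower after SP. At least 2-fold changes were found for 1038 genes higher and 1083 lower. In 5434 of the called genes the 4 SP arrays did not overlap the 4 PBS arrays, and in 6914 (32.9%) of all 21024 genes. For a gene not chosen by its p, 1 of the 35 splits of 8 arrays gives this separation by chance. Called genes were chosen for a small p, so their separation is no further support. The other large rises were those of Mreg (51.5-fold), the innate signalling kinase Ikbke (34.6-fold), Serpina3m (at least 32.4-fold), Tm4sf19 (31.2-fold), the interferon-induced gene Ifi205 (31-fold) and the matrix protein gene Tnc (30.8-fold). The other large falls were those of Chst4 (13.7-fold), Lgi3 (12.4-fold), Sec14l3 (12.4-fold), Aox3 (12-fold), Slurp1 (10.3-fold), the dendritic cell lectin Cd209a (10.1-fold), Pon1 (9.39-fold) and the carboxylesterase Ces1g (at least 9.33-fold). In the 4 Nrf2null_PBS arrays Sec14l3 (12.17, 10.91, 12.09 and 11.31) followed the mean gene-centred value of the epithelial markers (1.23, 0.264, 1.21 and 0.34). Lgi3 and Kcnj13 were also highest in replicates 1 and 3 of that group. RNA of epithelium may account for such falls, which was not tested. Among the rises, Serpina3m in WT_SP replicates 1 to 4 (8.98, 9.60, 7.87 and 7.37) went with the fibroblast marker Pdgfra (10.19, 10.69, 9.23 and 8.49). Tnc, and Il6 and Slc39a14 described below, were also highest in replicates 1 and 2, while Mreg (11.72, 11.61, 11.63 and 11.81) was not. RNA of fibroblasts may account for such rises, which was not tested either.

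Interferon genes rose most uniformly in WT. All 16 measured members of the interferon gamma response rose, with a median of 2.95 (camera adjusted p = 3.25e-21, and adjusted p = 0.0413 with an estimated correlation). Besides Gbp5, these included Socs1, a feedback inhibitor of cytokine signalling (4.80), Gbp3 (3.82) and Iigp1 (3.78). Of 23 type I interferon genes, 22 rose and 1 was not called, and 23 rose when adjusted over the list alone. Their median was 1.98 (camera adjusted p = 7.82e-23, and adjusted p = 0.0795 with an estimated correlation). Ifit2 rose by 3.50, Ifi44 by 2.86 and Ifit1 by 2.77 on the log2 scale.

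Genes for signalling proteins of inflammation rose as well. Of 19 proinflammatory cytokines, 15 rose and 4 were not called (16 rose adjusted over the list alone), with a median of 1.84 (camera adjusted p = 3.96e-11, and adjusted p = 0.0987 with an estimated correlation). Csf3, the growth factor of neutrophils, rose at least 27.9-fold, Il6 24.1-fold, Il1a 23.6-fold and Il23a 19.6-fold. Of 19 chemokines, 16 rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 1.94 (camera adjusted p = 2.09e-11, and adjusted p = 0.0795 with an estimated correlation). Cxcl10 rose 23.7-fold, Cxcl5 14.2-fold and Ccl4 13-fold. Of 20 NF-kappaB feedback and target genes, 16 rose (17 adjusted over the list alone), with a median of 1.40 (camera adjusted p = 9.15e-12, and adjusted p = 0.14 with an estimated correlation). Tnip1 rose by 2.92, Traf1 by 2.74, Nfkbie by 2.63 and the mitochondrial superoxide dismutase Sod2 by 2.57. Of 17 pattern recognition receptors, 10 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.72 (camera adjusted p = 6.57e-04, and adjusted p = 0.563 with an estimated correlation). The DNA sensor Tlr9 rose by 3.53 and Nod2 by 2.90, while the flagellin receptor Tlr5 fell by 2.22.

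Of 24 apoptosis regulators, 18 rose and 6 were not called, with 18 adjusted over the list alone and a median of 0.98 (camera adjusted p = 5.20e-10, and adjusted p = 0.0987 with an estimated correlation). The members with the largest changes act against cell death: Bcl2a1a rose 21.8-fold, Bcl2a1d 10.8-fold and Cflar 4.28-fold. Of 14 metal handling genes, 7 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0137, and adjusted p = 0.16 with an estimated correlation). The zinc importer Slc39a14 rose 5.8-fold, the haem-degrading enzyme Hmox1 2.92-fold and the metallothionein Mt2 2.58-fold. Of 17 complement and scavenger receptor genes, 8 rose and 3 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.0172, and adjusted p = 0.531 with an estimated correlation). Fcgr1, the high-affinity IgG receptor, rose 10.3-fold and complement factor Cfb 7.44-fold, while the mannose receptor Mrc1 fell 5.86-fold. Of 18 endoplasmic reticulum stress genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone). That list's camera adjusted p was 0.0485, against adjusted p = 0.361 with an estimated correlation, and the call also ended without any 1 of 8 arrays (adjusted p between 0.0516 and 0.0993): WT_PBS replicates 3 and 4, WT_SP replicates 1 and 2, Nrf2null_PBS replicate 4 and Nrf2null_SP replicates 1, 3 and 4.

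Some members of the secondary and tertiary granule list and of the lipid mediator list fell in WT. Of 13 secondary and tertiary granule genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 0.0172, and adjusted p = 0.665 with an estimated correlation; without WT_PBS replicate 4 the median was -0.474 and the adjusted p 0.0814). Padi4, in the list though it encodes an enzyme that citrullinates histones, fell 4.01-fold, Anxa1 2.31-fold and the gelatinase Mmp9 1.6-fold, while Lcn2 rose 1.28-fold. Of 11 lipid mediator genes, 6 fell and 2 rose (7 and 2 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 0.0386, and adjusted p = 0.177 with an estimated correlation). The leukotriene enzymes Ltc4s and Alox5 fell 3.24-fold and 2.6-fold. Of 15 neutrophil markers, 7 fell (9 fell and 1 rose adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.00207, and adjusted p = 0.563 with an estimated correlation). Lrg1 fell by 0.97 and S100a9 by 0.89. Csf3r, the receptor for the neutrophil growth factor, fell by 0.42, with adjusted p = 0.066 when array medians were centred.

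Markers of other lung cells moved in both directions after SP in WT, beside all of these groups. Of 19 epithelial markers, 13 fell (15 adjusted over the list alone), with a median of -0.995 (camera adjusted p = 8.56e-06, and adjusted p = 0.471 with an estimated correlation). Sftpc, a surfactant protein, was at 12.80 ± 0.08 (SD, n = 4) in WT_PBS and 11.47 ± 0.34 in WT_SP, and the airway gene Cyp2f2 fell 3.69-fold and the water channel Aqp5 4.03-fold. Of 15 B cell markers, 12 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -1.37 (camera adjusted p = 5.16e-06, and adjusted p = 0.352 with an estimated correlation). Fcmr fell 4.72-fold and Bank1 4.48-fold. Of 19 alveolar macrophage markers, 10 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0147, and adjusted p = 0.665 with an estimated correlation). Mrc1 fell 5.86-fold and Cidec 6.2-fold. T and NK cell markers rose: 11 of 23 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 9.61e-05, and adjusted p = 0.563 with an estimated correlation). Il7r rose 6.42-fold and Cd8a 3.19-fold. Of 16 fibroblast and smooth muscle markers, 8 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0113, and adjusted p = 0.665 with an estimated correlation). Pdgfra rose 6.47-fold and the collagen gene Col1a2 2.64-fold, the latter with adjusted p between 0.0606 and 0.0785 without WT_PBS replicate 4, WT_SP replicate 1 or WT_SP replicate 2. The calls of the alveolar macrophage, fibroblast, metal handling, complement, secondary granule, lipid mediator and endoplasmic reticulum stress lists also ended when dim probe sets were filtered out, with adjusted p between 0.0626 and 0.128. The complement list had one of 0.0618 with array medians centred, the endoplasmic reticulum stress list of 0.158 with quantile normalization and the lipid mediator list of 0.0524 with 13 arrays, and the fibroblast and secondary granule lists of 0.0641 and 0.0561 by fry.

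The second comparison asked which genes SP changed in Nrf2 null neutrophils. By camera, interferon, NF-kappaB, cytokine and chemokine genes rose as groups, and epithelial, B cell and alveolar macrophage markers fell. None of these calls held with an estimated correlation (adjusted p between 0.0904 and 0.109 for the rises and between 0.299 and 0.51 for the falls). Cxcl9 rose 66.7-fold (log2 change 6.06, SE 0.275, n = 4 and 4, adjusted p = 4.94e-10), and Gbp5 rose 58-fold (SE 0.111, adjusted p = 7.53e-14). Il23a, a subunit of interleukin 23, rose 52.8-fold (SE 0.619, adjusted p = 4.06e-06) and Cxcl10 47.7-fold (SE 0.3, adjusted p = 2.94e-09). Sprr1a, an epithelial cornified envelope gene, fell 29.5-fold (SE 0.561, adjusted p = 7.36e-06), and the macrophage folate receptor Folr2 fell 20-fold (SE 0.233, adjusted p = 2.97e-09).

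In Nrf2 null, 9145 genes (43.5%) were called, with 4016 higher and 5129 lower after SP, or 11738 and 2997 with array medians centred. At least 2-fold changes were found for 1252 genes higher and 2090 lower. In 7190 of the called genes the SP and PBS arrays did not overlap, and in 7779 (37%) of all genes. The other large rises were those of Mreg (60-fold), Hamp (at least 58.3-fold), Saa3 (52.7-fold), Socs1 (43.3-fold), Tm4sf19 (42.3-fold) and the activin subunit gene Inhba (39-fold). Other large falls were those of Sec14l3 (27.1-fold), Lgi3 (21.7-fold), Chst4 (18.1-fold), Chad (16.1-fold), Pon1 (15.6-fold), the mesothelial gene Upk3b (15.4-fold) and Kcnj13 (15.1-fold). As for WT, RNA of epithelium may account for some of these falls, which was not tested. With a covariate for RNA of other lung cells, which itself differed between the PBS and SP arrays, 4185 genes were called.

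All 23 type I interferon genes rose in Nrf2 null, with a median of 2.69 (camera adjusted p = 1.97e-20, and adjusted p = 0.109 with an estimated correlation). Ifi205 rose 31.4-fold, Ifit2 20.4-fold, Ifit1 11-fold and Xaf1 10.2-fold. All 16 interferon gamma response genes rose, with a median of 3.80 (camera adjusted p = 3.89e-17, and adjusted p = 0.0904 with an estimated correlation). Cd274, which encodes the checkpoint ligand PD-L1, rose 22-fold and Gbp3 21.4-fold. All 20 NF-kappaB feedback and target genes rose, with a median of 2.33 (camera adjusted p = 5.24e-13, and adjusted p = 0.109 with an estimated correlation). Nfkbie rose 12-fold, Cd40 10.3-fold, Tnip1 10.2-fold and Traf1 8.99-fold. In these 3 lists the counts adjusted over the list alone were the same. Of 19 proinflammatory cytokines, 18 rose and 1 was not called, also adjusted over the list alone, with a median of 2.61 (camera adjusted p = 2.91e-11, and adjusted p = 0.109 with an estimated correlation). Il12a rose 33.7-fold, Il1a 32.7-fold and Csf3 at least 31.9-fold. Of 19 chemokines, 14 rose and 2 fell, also adjusted over the list alone, with a median of 2.31 (camera adjusted p = 2.99e-08, and adjusted p = 0.109 with an estimated correlation). Ccl4 rose 31.2-fold and the neutrophil chemokine Cxcl1 17.3-fold.

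Of 24 apoptosis regulators in Nrf2 null, 19 rose and 1 fell, also adjusted over the list alone, with a median of 1.44 (camera adjusted p = 6.02e-10, and adjusted p = 0.109 with an estimated correlation). Bcl2a1a rose 23.8-fold, Bcl2a1d 14.2-fold and Pmaip1, which promotes cell death, 6.55-fold. Of 17 pattern recognition receptors, 10 rose and 2 fell (14 and 2 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 2.20e-04, and adjusted p = 0.51 with an estimated correlation). Tlr9 rose 14-fold, Nod2 13.8-fold and Tlr2 4.43-fold. Of 17 complement and scavenger receptor genes, 10 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.0313, and adjusted p = 0.51 with an estimated correlation). Of 24 oxidative phosphorylation genes, 15 fell and 2 rose (17 and 2 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.00397, and adjusted p = 0.523 with an estimated correlation). With array medians centred, which moved the median of all genes in this contrast from 0.04 to 0.39, the median of that list was 0.03. Ndufa4 and Ndufa8 fell 1.76-fold and 1.73-fold, while cytochrome c (Cycs) rose 1.97-fold. Of 19 cholesterol and fatty acid synthesis genes, 9 fell (9 fell and 1 rose adjusted over the list alone), with a median of -0.55 (camera adjusted p = 0.00665, and adjusted p = 0.574 with an estimated correlation). The desaturases Scd2 and Scd1 fell 4.74-fold and 3.39-fold, and the synthase Fasn 3.07-fold. Of 24 cell cycle genes, 11 fell and 2 rose (12 and 2 adjusted over the list alone; camera adjusted p = 0.0269, and adjusted p = 0.527 with an estimated correlation; 0.0723 without Nrf2null_PBS replicate 2 and 0.0659 without Nrf2null_SP replicate 4), and with quantile normalization the median was -0.15, against -0.43 (adjusted p = 0.384). With the covariate for other cells the falls of Ndufa4, Scd1 and Fasn were smaller and less precise, at -0.52 (SE 0.275), -1.16 (SE 0.412) and -0.81 (SE 0.468), and were no longer called (adjusted p = 0.22, 0.0641 and 0.266), nor were the oxidative phosphorylation, cholesterol and cell cycle lists (adjusted p = 0.0626, 0.069 and 0.652).

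Markers of other lung cells again moved in both directions. Of 19 epithelial markers, 17 fell, also adjusted over the list alone, with a median of -1.46 (camera adjusted p = 1.10e-07, and adjusted p = 0.365 with an estimated correlation). Aqp5 fell 6.94-fold and Cyp2f2 6.36-fold. Of 15 B cell markers, 13 fell, also adjusted over the list alone, with a median of -1.91 (camera adjusted p = 4.26e-07, and adjusted p = 0.299 with an estimated correlation). Fcmr fell 6.69-fold and the antigen receptor chain Cd79a 5.95-fold. Of 19 alveolar macrophage markers, 12 fell and 2 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.00135, and adjusted p = 0.51 with an estimated correlation), with Mrc1 down 14-fold and Krt19, also a keratin of epithelium, down 8.96-fold. Of 18 endothelial markers, 10 fell, also adjusted over the list alone (camera adjusted p = 0.00665, and adjusted p = 0.663 with an estimated correlation), with Ednrb down 6.87-fold and Tmem100 down 4.65-fold. Of 23 T and NK cell markers, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.94 (camera adjusted p = 8.14e-04, and adjusted p = 0.527 with an estimated correlation). Their mean gene-centred score was -0.387 in Nrf2null_SP replicate 4, within the -0.447 to -0.208 of the Nrf2null_PBS arrays, and 0.542 to 1 in the other 3 Nrf2null_SP arrays. Gzmb, a cytotoxic protease, rose 4.13-fold and Il7r 3.9-fold. Of 15 neutrophil markers, 8 fell and 1 rose (8 and 2 adjusted over the list alone), and the list was not called (median -0.30, or 0.05 with array medians centred; camera adjusted p = 0.166). Of 16 fibroblast and smooth muscle markers, 4 fell and 3 rose, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.76). Inmt and Dcn fell 8.48-fold and 2.92-fold, and with the covariate for other cells Inmt had a log2 change of 0.29 (adjusted p = 0.842) and Dcn of -0.85 (adjusted p = 0.181). With 13 arrays, after WT_PBS replicate 3 and Nrf2null_PBS replicates 1 and 3 had been left out, Inmt had a log2 change of -2.80 (adjusted p = 0.0575). That of the endothelial list was 0.136 with 13 arrays and 0.652 with the covariate, under which Tmem100 had a log2 change of -1.29 (SE 0.581, against 0.395 without it; adjusted p = 0.145). Filtering out dim probe sets ended the calls of the oxidative phosphorylation, cell cycle, cholesterol and endothelial lists, with adjusted p between 0.112 and 0.443. With 13 arrays the oxidative phosphorylation, cholesterol and complement lists had medians of -0.22, -0.10 and 0.39, against -0.32, -0.55 and 0.60 (adjusted p = 0.0845, 0.269 and 0.0531). The complement list had an adjusted p of 0.0531 with quantile normalization, 0.0556 with the covariate and 0.368 with array medians centred, and the batch term gave 0.107 for the cholesterol list and 0.114 for the endothelial list.

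**Figure D2:**
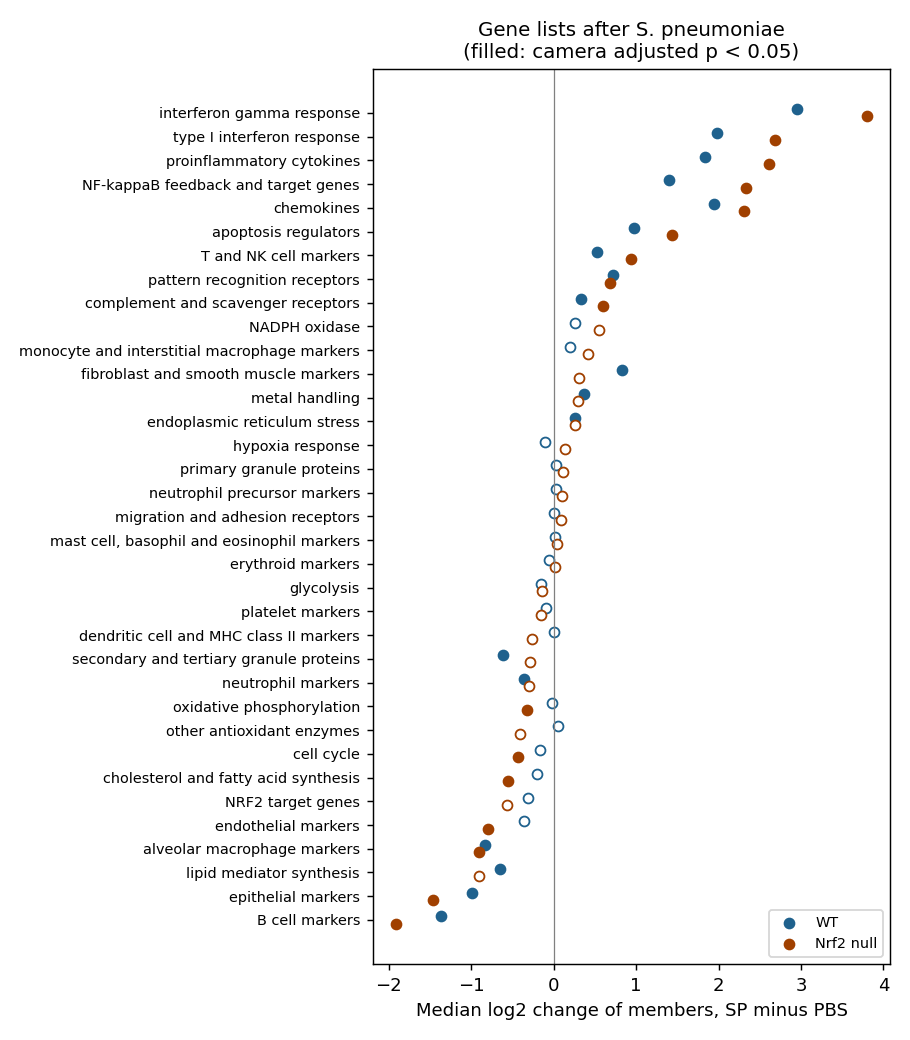
Each point gives the median log2 change (x axis, SP minus PBS) of a gene list (y axis) in WT or in Nrf2 null, filled where the camera adjusted p was below 0.05. The interferon gamma response lies furthest right, at 2.95 in WT and 3.80 in Nrf2 null, and B cell markers furthest left, at -1.37 and -1.91.

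The SP responses of both genotypes were largely shared. Of the called genes, 4775 changed in the same direction in both genotypes and 8 in opposite directions. Among genes higher after SP, 2172 were called in both, against 537.7 for independent lists, and among genes lower after SP the counts were 2603 and 740.9. The log2 changes had a Pearson r of 0.891 across genes, which are not independent replicates. WT alone called 1069 genes and Nrf2 null alone 4362, counts that do not test a difference between the genotypes.

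The third comparison asked which genes differed between Nrf2 null and WT after PBS, without bacteria. NRF2 target genes were lower as a group in Nrf2 null, and the largest called difference was that of the carboxylesterase Ces1g. Nfe2l2 differed by -0.14 (SE 0.0817, adjusted p = 0.611). Ces1g was at least 8.33-fold lower in Nrf2 null (log2 difference -3.06, SE 0.336, n = 4 and 4, adjusted p = 0.0021), at 7.02 ± 0.98 (SD) in WT_PBS and 3.96 ± 0.29 in Nrf2null_PBS. Its neighbour Ces1f was at least 1.75-fold lower (SE 0.094, adjusted p = 0.00278), at 4.47 ± 0.17 in WT_PBS. Srxn1, which encodes sulfiredoxin, an NRF2 target that repairs peroxiredoxins, was 2.25-fold lower (SE 0.175, adjusted p = 0.0335).

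The arrays of the 2 genotypes after PBS did not overlap for 690 (3.28%) of all genes. Ces1g, Ces1f and Srxn1 were 3 of 5 called genes after PBS, 4 lower and 1 higher, all without such overlap. The others were Gm3893, a predicted gene named here after its values were seen (4.97-fold lower, adjusted p = 0.0021), and Pisd-ps3, a pseudogene (1.79-fold higher, adjusted p = 0.0299). At an unadjusted p under 0.05, 1912 genes differed. Of 31 measured NRF2 target genes, 1 was called lower, and 10 were lower adjusted over the list alone. Their median was -0.37 (camera adjusted p = 1.68e-10, and adjusted p = 0.00353 with an estimated correlation). Nqo1 had a difference of -1.92 (SE 0.326, adjusted p = 0.0575) and Gclm, the modifier subunit of the glutathione synthesis enzyme, of -0.54 (adjusted p = 0.454). In the type I interferon list, no member was called, 1 was lower adjusted over the list alone, and the median was -0.24 (camera adjusted p = 3.89e-07, and adjusted p = 0.63 with an estimated correlation). Isg15 differed by -1.15 (adjusted p = 0.246). In the proinflammatory cytokine list, where 1 member was lower adjusted over the list alone, the median was -0.44 (camera adjusted p = 0.00142, and adjusted p = 0.634 with an estimated correlation; 0.0523 without WT_PBS replicate 1), and Il23a differed by -1.29 (adjusted p = 0.557). Il23a lay at 7.54 and 6.64 in WT_PBS replicates 1 and 2, at 4.03 and 4.04 in replicates 3 and 4, and between 4.09 and 4.54 in the Nrf2null_PBS arrays. Of 15 B cell and 19 epithelial markers, none was called, and the lists had medians of 0.25 and 0.36 (camera adjusted p = 1.83e-04 for each, and adjusted p = 0.633 and 0.634 with an estimated correlation; 0.0506 for B cells without WT_PBS replicate 3). The neutrophil marker list was also called by camera, with mean gene-centred scores of 0.222 in WT_PBS and 0.0442 in Nrf2null_PBS. Its call ended without Nrf2null_PBS replicate 1 or 3 (camera adjusted p from 0.0519 to 0.0647) and with an estimated correlation.

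The count of 5 rests on few arrays. It was 274 without Nrf2null_PBS replicate 2, 10 without Nrf2null_PBS replicate 1, 10 with 13 arrays, 3422 with array weights, 1 in a fit of the compared groups alone, and 3 without WT_PBS replicate 2, WT_SP replicate 4, Nrf2null_PBS replicate 4 or Nrf2null_SP replicate 2. The calls of Srxn1 and Pisd-ps3 each ended without any 1 of 8 arrays (WT_PBS 2 and 3, WT_SP 4, Nrf2null_PBS 3 and 4 and Nrf2null_SP 2 for both genes, WT_PBS 1 and WT_SP 1 for Srxn1, WT_PBS 4 and Nrf2null_PBS 1 for Pisd-ps3), with adjusted p from 0.0544 to 0.13 and from 0.0512 to 0.107, and in the fit of the compared groups alone Ces1g, Ces1f, Srxn1 and Pisd-ps3 had the same differences with adjusted p of 0.372, 0.231, 0.676 and 0.231. With no variance moderation Srxn1 and Pisd-ps3 had adjusted p of 0.116 and 0.0688, and with array medians centred Pisd-ps3 differed by 0.73 (adjusted p = 0.0995). With 13 arrays the type I interferon, cytokine and epithelial lists had smaller medians, of -0.06, -0.16 and 0.03 (adjusted p = 0.273, 0.157 and 0.727). Srxn1 and Pisd-ps3 then differed by -0.97 and 0.70 (adjusted p = 0.199 and 0.325), and with the covariate for other cells Srxn1 differed by -1.15 (SE 0.192, against 0.175 without it; adjusted p = 0.153). With the replicate number as a block Srxn1 and Pisd-ps3 each had an adjusted p of 0.0809.

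The fourth comparison asked which genes differed between Nrf2 null and WT after SP. The 3 largest falls were those of Nqo1, Gsta3 and Srxn1, genes of detoxification and antioxidant defence in the NRF2 target list. Nfe2l2 differed by -0.31 (SE 0.0817, adjusted p = 0.17). Nqo1 was 11.1-fold lower in Nrf2 null (log2 difference -3.47, SE 0.326, n = 4 and 4, adjusted p = 1.89e-04), at 8.31 ± 0.43 (SD) in WT_SP and 4.84 ± 0.71 in Nrf2null_SP. Srxn1 was 4.46-fold lower (SE 0.175, adjusted p = 4.10e-05), the glutathione transferase Gsta3 4.62-fold (SE 0.316, adjusted p = 0.0068) and Gclm 3.33-fold (SE 0.176, adjusted p = 3.68e-04). Creg1, a secreted glycoprotein, was 2.89-fold lower (SE 0.121, adjusted p = 4.10e-05).

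After SP, 60 genes were called, 31 higher and 29 lower in Nrf2 null. In all 60 the 4 arrays of each genotype did not overlap, and in 2159 (10.3%) of all genes. The counts higher and lower were 63 and 25 without Nrf2null_SP replicate 4, 51 and 20 with quantile normalization, 53 and 24 with array medians centred and 10 and 24 in a fit of the compared groups alone. Of the 28 with at least a 2-fold difference, 19 were lower and 9 higher. Srxn1 and Gm3893 were called both after PBS and after SP, in the same direction. Of the 29 lower genes 22 were also lower after PBS, and of the 31 higher genes 20 were also higher after PBS, by sign alone. Over all genes 38.2% had the same sign in both comparisons (Pearson r -0.158), and 52.83% were lower after PBS. The differences after PBS were -0.33 for Gsta3 (adjusted p = 0.762), -0.13 for Creg1 (adjusted p = 0.758) and -0.17 for Slc22a4 (adjusted p = 0.849). Further falls after SP were those of the ergothioneine transporter Slc22a4 (4.41-fold), Esd (3.79-fold), Ptgr1, an enzyme that inactivates lipid mediators (3.65-fold), Rnf128 (3.56-fold) and the platelet factor Pf4 (2.45-fold). Slpi, the only neutrophil marker of 15 that was called, was 1.41-fold lower (adjusted p = 0.0369). The 10 largest rises were among genes with Nrf2null_SP means from 4.94 to 9.67, against a background of 3.61. Among them, Adgrb1 was 3.06-fold higher, the odorant receptor gene Olfr1394 3.04-fold, Heatr9 2.73-fold, Olfr1395 2.39-fold, Pdzk1ip1 2.36-fold, Fap 2.2-fold, Ctrl 1.9-fold, Tmem236 1.85-fold and Tnfsf18 at least 1.83-fold.

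Of the 31 NRF2 target genes, 4 were called lower after SP, 18 were lower adjusted over the list alone and none was higher. Their median was -0.72 (camera adjusted p = 1.28e-18, and adjusted p = 2.29e-04 with an estimated correlation). In the list of other antioxidant enzymes, 2 of 15 were lower adjusted over the list alone, with a median of -0.12, or 0.03 with array medians centred (camera adjusted p = 0.00579, and adjusted p = 0.144 with an estimated correlation). The type I interferon and interferon gamma lists had no called member, and medians of 0.25 and 0.28 (camera adjusted p = 2.15e-05 and 4.03e-04, and adjusted p = 0.599 for each with an estimated correlation). Markers of fibroblasts and endothelium, again with no called member, had medians of -0.68 and -0.49 (camera adjusted p = 2.15e-05 for each, and adjusted p = 0.599 and 0.732 with an estimated correlation). With array medians centred, the median difference of all genes after SP was 0.14.

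The count of 60 fell with most omissions of an array: to 33, 29, 34 and 30 without WT_PBS replicates 1 to 4, to 27, 30, 23 and 33 without WT_SP replicates 1 to 4, and to 39 and 31 without Nrf2null_SP replicates 2 and 3, while 34 genes were called with the covariate for other cells and 34 in a fit of the compared groups alone. Calls of single genes also ended without single arrays: that of Pf4 without WT_SP replicate 1 or 3 (adjusted p = 0.0561 and 0.0591), that of Tnfsf18 without WT_PBS 2 or 4, WT_SP 2, 3 or 4 or Nrf2null_SP 2 (up to 0.117), that of Esd without WT_PBS 1 or 4, WT_SP 1, 3 or 4 or Nrf2null_SP 1, 2 or 3 (up to 0.102), that of Ptgr1 without WT_PBS 1, 2 or 4, WT_SP 1, 3 or 4 or Nrf2null_SP 1, 3 or 4 (up to 0.144), and those of Slpi, Pdzk1ip1, Ctrl and Adgrb1 without any 1 of the WT arrays or Nrf2null_SP 1 or 3, and further without Nrf2null_SP 2 (not Pdzk1ip1), Nrf2null_SP 4 (Pdzk1ip1 and Ctrl), Nrf2null_PBS 3 (Slpi and Adgrb1) or Nrf2null_PBS 1 or 2 (Adgrb1), up to 0.141, 0.144, 0.165 and 0.169. In the fit of the compared groups alone, with the same differences, Heatr9, Olfr1395, Fap, Pdzk1ip1, Adgrb1, Tnfsf18, Esd, Pf4 and Slpi had adjusted p of 0.0989, 0.0829, 0.0721, 0.0744, 0.119, 0.108, 0.0978, 0.0908 and 0.0811. With the covariate for other cells 6 of the calls named above ended, with differences of similar size: Ptgr1 at -1.69 (SE 0.376, against 0.338 without it; adjusted p = 0.139), Pf4 at -1.08 (SE 0.196 against 0.202; 0.0503), Adgrb1 at 1.80 (SE 0.348 against 0.314; 0.0689), Ctrl at 0.84 (SE 0.2 against 0.178; 0.176), Pdzk1ip1 at 1.09 (SE 0.249 against 0.228; 0.148) and Tnfsf18 at 0.93 (SE 0.172 against 0.152; 0.0561). The fibroblast list then had an adjusted p of 0.0615. With the replicate number as a block Adgrb1 and Ctrl had adjusted p of 0.0689 and 0.0565. With no variance moderation and the same differences, Adgrb1, Ctrl, Esd, Pdzk1ip1, Ptgr1 and Tnfsf18 had adjusted p of 0.113, 0.0968, 0.0815, 0.0857, 0.0857 and 0.0588. Esd differed by -1.68 with quantile normalization (adjusted p = 0.0599), Slpi by -0.35 with array medians centred (0.271), Ctrl by 0.93 with an intensity trend and robust prior (0.0517) and Adgrb1 by 1.62 with 13 arrays (0.0558). With dim probe sets filtered out Slpi had one of 0.0522 and the other antioxidant list of 0.158.

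**Figure D3:**
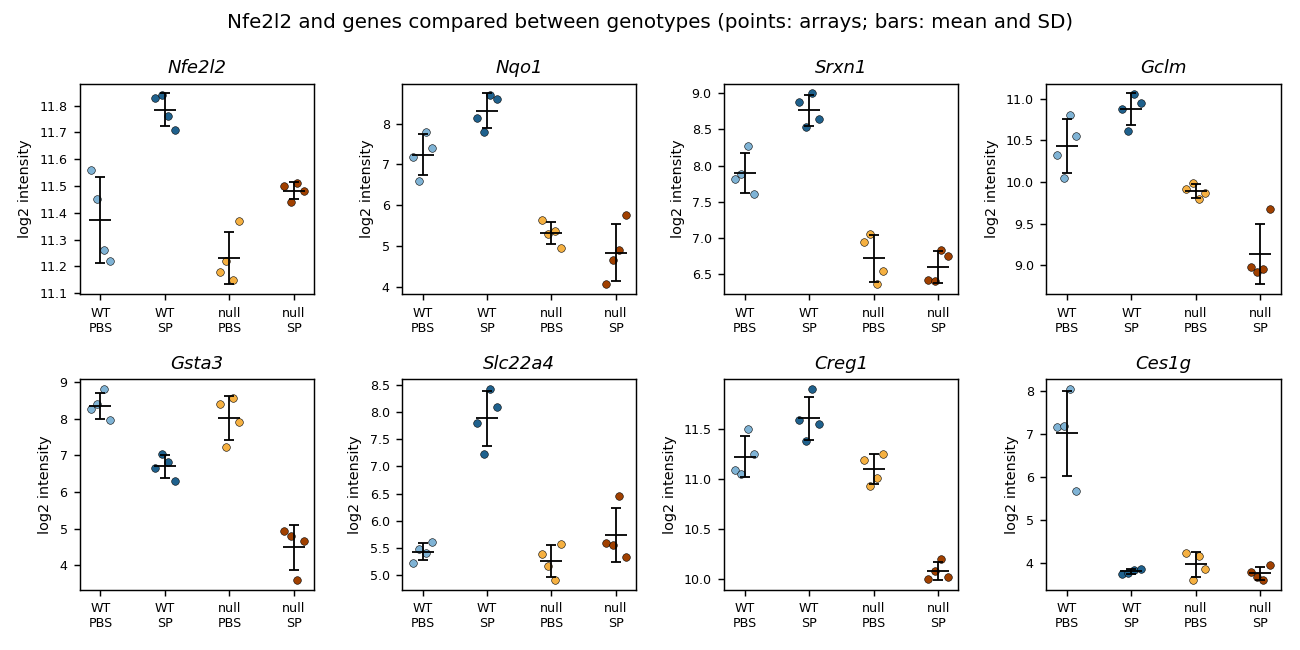
Points are the log2 levels (y axis, with its own range in each panel) of Nfe2l2, Nqo1, Srxn1, Gclm, Gsta3, Slc22a4, Creg1 and Ces1g in each of the 16 arrays, by group (x axis), with bars for the mean and SD (n = 4). Nqo1 lies at 8.31 ± 0.43 in WT_SP and 4.84 ± 0.71 in Nrf2null_SP, and Nfe2l2 at 11.79 ± 0.06 and 11.48 ± 0.03.

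The last comparison asked which SP responses differed between the genotypes. Creg1 was the gene called, with SP responses that differed by -1.40 (2.64-fold, SE 0.171, 4 arrays per group, adjusted p = 0.0155). Its level was 11.22 ± 0.20 (SD) in WT_PBS, 11.61 ± 0.22 in WT_SP, 11.09 ± 0.15 in Nrf2null_PBS and 10.07 ± 0.09 in Nrf2null_SP. By camera, interferon and NF-kappaB genes had larger rises in Nrf2 null than in WT as groups, calls that did not hold with an estimated correlation (adjusted p between 0.461 and 0.476). Levels after PBS enter these differences. The mean gene-centred NF-kappaB score was -0.681 in WT_PBS and -1.1 in Nrf2null_PBS, and 0.785 in WT_SP and 1 in Nrf2null_SP. It was -0.26 and -0.482 in WT_PBS replicates 1 and 2, against -1.02 and -0.963 in replicates 3 and 4. Nfe2l2 differed by -0.16 (adjusted p = 0.465).

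In this contrast 3097 genes had an unadjusted p under 0.05. The next genes, none of them called, were Olfr1394 (difference 1.90), Ces1f (0.85), Ces1g (3.01) and Tma16 (-1.18), each with adjusted p = 0.063. Ces1f and Ces1g were at or under 4.08 in all groups but WT_PBS, and Olfr1394 in both PBS groups, so the background limits these 3 differences. Of 23 type I interferon genes, none was called over all genes and 9 had larger responses in Nrf2 null adjusted over the list alone. Their median difference was 0.57 (camera adjusted p = 3.37e-09, and adjusted p = 0.461 with an estimated correlation). Isg15 and Oasl1 differed by 1.32 and 0.95 (adjusted p = 0.286 and 0.319). For NF-kappaB genes the median was 0.53, with 1 larger response adjusted over the list alone (camera adjusted p = 2.00e-06, and adjusted p = 0.476 with an estimated correlation). For 31 NRF2 target genes, 5 had lower responses adjusted over the list alone, and the median was -0.18, or 0.08 with array medians centred, which moved the median of all genes to 0.27 (camera adjusted p = 0.0148, and adjusted p = 0.461 with an estimated correlation). Gsta3 and Nqo1 differed by -1.88 and -1.55 (adjusted p = 0.271 and 0.286). Epithelial, B cell and fibroblast markers had median differences of -0.65, -0.50 and -0.77 (camera adjusted p = 0.00132, 0.00132 and 0.00395, and adjusted p = 0.714 for each with an estimated correlation). Pf4, a platelet marker, differed by -1.60 (adjusted p = 0.127).

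The call of Creg1 ended without WT_PBS replicate 2, WT_SP replicate 1 or 4, Nrf2null_PBS replicate 4 or Nrf2null_SP replicate 1 (adjusted p between 0.0515 and 0.0659, and no gene was then called), with no variance moderation (0.0669) and with the covariate for other cells, where the difference was -1.38 (SE 0.208, against 0.171 without it; adjusted p = 0.179). The number of genes called was 12 without Nrf2null_SP replicate 4, 5 without Nrf2null_PBS replicate 2 or Nrf2null_SP replicate 2, 2 without WT_PBS replicate 1 or 4 or Nrf2null_PBS replicate 1, and 3423 with array weights. The NRF2 target list had an adjusted p of 0.207 with dim probe sets filtered out, the epithelial list of 0.096 with 13 arrays and 0.499 with the covariate, and the fibroblast list a median of 0.04 with the covariate for other cells (adjusted p = 0.567). Of the lists called by camera, 18 in WT, 16 in Nrf2 null, 14 after PBS, 14 after SP and 16 for the difference of responses, those that held with an estimated correlation were the interferon gamma response in WT and the NRF2 target genes after PBS and after SP.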

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

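Of the tests below, those with 13 arrays, that of a single lower share of neutrophils and that of swapped labels were chosen after the result was seen. An array was set apart when its gap to the nearest array of its group was a large enough part of the group's range by Dixon's test at the 95% level, which chance gives in about 1 of 20 groups. This was so for 17 of 386 gene and group combinations (4.4%) and for 11 of 140 list scores (7.86%). Nrf2null_SP replicate 4 held 5 of these values.

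In WT_SP, replicate 3 was low for Hamp (8.65) and Oasl1 (11.07), replicate 1 high for Hk2 (8.73) and Tma16 (8.58), replicate 4 low for Ltc4s (3.67) and replicate 2 high for Mt2 (11.95). In WT_PBS, replicate 3 was low for Padi4 (9.94) and high for Aqp5 (10.14), replicate 4 low for Col1a2 (5.67) and replicate 2 high for Olfr1394 (4.54). In Nrf2null_PBS, replicate 2 was high for Il1a (9.22) and replicate 4 low for Traf1 (7.40). In Nrf2null_SP, replicate 4 was low for Ndufa4 (7.05) and high for Anxa1 (11.65), Esd (6.92) and Gclm (9.68), and replicate 2 was high for Cd79a (7.73).

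Mean gene-centred scores of lists that stood apart were those of NRF2 targets in Nrf2null_SP replicate 4 (-0.507), NADPH oxidase in WT_SP replicate 4 (0.177), primary granules in WT_PBS replicate 4 (-0.0217), pattern recognition receptors in WT_PBS replicate 3 (-0.566), hypoxia in Nrf2null_PBS replicate 2 (-0.0354) and dendritic cells in Nrf2null_PBS replicate 4 (0.331). The others were B cells in Nrf2null_SP replicate 2 (-0.364), epithelium in WT_SP replicate 2 (-0.333), erythroid cells in Nrf2null_PBS replicate 3 (0.774), platelets in WT_SP replicate 2 (-0.159) and neutrophil precursors in Nrf2null_PBS replicate 1 (-0.348).

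SP responses differed between the genotypes by the test of the difference for Creg1 (-1.40) and for 16 lists. Median differences, Nrf2 null minus WT, were positive for proinflammatory cytokines (0.557), NF-kappaB genes (0.534), type I interferon (0.573), interferon gamma (0.549), pattern recognition receptors (0.279), migration receptors (0.264) and apoptosis regulators (0.365). They were negative for NRF2 targets (-0.178), other antioxidant enzymes (-0.178), oxidative phosphorylation (-0.336), cholesterol synthesis (-0.265), alveolar macrophages (-0.183), B cells (-0.502), epithelium (-0.647), endothelium (-0.41) and fibroblasts (-0.772). None of the 16 held with an estimated correlation, nor with fry (adjusted p 0.0848 to 0.563). With array medians centred, the medians of NRF2 targets, other antioxidant enzymes and alveolar macrophages were 0.0753, 0.0747 and 0.0701. Leaving out single arrays ended the call of 5 of the 16: other antioxidant enzymes without WT_PBS 2 or Nrf2null_SP 1 or 3 (adjusted p 0.0506 to 0.0658), pattern recognition receptors without Nrf2null_PBS 1 or 3 (0.0682 to 0.0904), cholesterol synthesis without WT_PBS 2, Nrf2null_PBS 1 or 3 or Nrf2null_SP 3 (0.0731 to 0.252), endothelium without WT_PBS 1, WT_SP 3 or Nrf2null_PBS 2 or 3 (0.0565 to 0.449), and alveolar macrophages without replicate 2 or 3 of WT_PBS or WT_SP, 2 or 4 of Nrf2null_PBS or 3 or 4 of Nrf2null_SP (0.0503 to 0.675). With the other-cell covariate the calls ended, at medians of 0.061 for migration receptors (adjusted p 0.297), 0.252 for pattern recognition receptors (0.099), -0.121 for alveolar macrophages (0.499), -0.226 for cholesterol synthesis (0.363), -0.227 for epithelium (0.499), 0.0214 for endothelium (0.982) and 0.0376 for fibroblasts (0.567). With 13 arrays they ended at 0.0565 for migration receptors (0.392), -0.017 for pattern recognition receptors (0.831), 0.00577 for cholesterol synthesis (0.831), -0.202 for epithelium (0.096) and -0.257 for endothelium (0.113). The filter on dim probe sets ended those of NRF2 targets, other antioxidant enzymes, alveolar macrophages, cholesterol synthesis and endothelium (0.192 to 0.558), and quantile normalization those of other antioxidant enzymes, alveolar macrophages and cholesterol synthesis (0.0529 to 0.135). In 12 of 100 reassignments of genotype within each inoculation, the real one included, at least 1 gene was called, so that chance cannot be excluded for the count of 1, and another reassignment gave 2602.

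Of the 10292 probe sets with no gene name here, which no comparison used, 1404 passed the threshold after SP in WT, 2778 after SP in Nrf2 null, 10 between genotypes after PBS and 27 between genotypes after SP. Splits of the 8 arrays of a comparison into 4 and 4 tested whether chance could give its count of named genes. For SP in WT 1 of 35 splits, the real one, gave as many as 5852 genes, and the highest other gave 0. For SP in Nrf2 null 1 of 35 gave as many as 9145, and the highest other gave 1. Between genotypes after SP 1 of 35 gave as many as 60, and the highest other gave 9. The real split stood alone for these 3 counts, and 1 of 35 is the smallest share this test can give. In the SP comparisons every other split mixes SP and PBS arrays, which widens the spread within groups. Few calls follow there whatever the cause, so those splits cannot decide the question.

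The first pattern is a larger SP response in Nrf2 null, with a median ratio of the log2 changes of 1.37 (jackknife SE 0.156) over 9838 genes. Without the 3 PBS arrays that stand apart the ratio over the same genes was 1.19 (SE 0.0652). Those genes were chosen with the 3 arrays included, and the reassignments below were not repeated without them. This ratio therefore cannot decide whether the 3 arrays account for all of the pattern. Nrf2null_SP replicate 4 alone does not account for the pattern over these genes, since without that array the ratio was 1.37 (SE 0.162). Chance assignment of arrays to genotypes stays open: 6 of 100 reassignments, the real one included, gave a ratio as far from 1, and the others lay between 0.721 and 1.48. Loss of NRF2, the biological explanation in the design, may also account for it and was not tested apart from these.

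The second pattern is the small number of genotype differences after PBS beside a strong structure of the PBS arrays. As many as 5 genes were called in 5 of 35 splits of the PBS arrays, so that chance cannot be excluded for this count. The highest other count was 2255, in the split that exchanges WT_PBS replicate 3 and Nrf2null_PBS replicate 2 and so puts the 3 arrays that stand apart in the same group, which points to a structure of the samples other than genotype. Swapped labels of those 2 arrays are excluded, since over the 29 genes lower in Nrf2 null after SP the mean of WT_PBS replicate 3 was 7.77 and that of Nrf2null_PBS replicate 2 was 7.14, against 7.5 to 7.77 in WT_PBS and 7.14 to 7.41 in Nrf2null_PBS. With 13 arrays 10 genes were called, and a processing batch or a difference in how the cells were taken could give this structure, but the labels name none.

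The third pattern is the movement of markers of other lung cells with SP, in cells selected by Ly6G beads, a selection meant to remove those cells. A single lower share of neutrophils after PBS would lower all of these markers after SP. In WT epithelial markers fell (-0.995, SE 0.19), while T and NK cell markers had a median of 0.526 (SE 0.191). Their scores were 0.178 to 0.475 in WT_SP against -0.649 to -0.292 in WT_PBS. In Nrf2 null their median was 0.943 (SE 0.389), but replicate 4 after SP showed no rise (-0.387). These rises argue against that explanation as the only one. They do not exclude it, since the list's calls did not hold with an estimated correlation. A rise of these genes within the cells present was not tested. Of the 3 PBS arrays that stand apart, only WT_PBS replicate 3 enters the WT comparison. It is excluded as the whole source there, since with the 3 arrays left out the epithelial median was -0.838 (SE 0.121). Nrf2 null, with replicates 1 and 3 after PBS among the 3, was left out of this test. A change in which other cells were carried along may explain the pattern, with the epithelial transcripts Sftpc at 12.80 and Cyp2f2 at 12.26 in WT_PBS, and the infection's effect on the lung was not tested apart from it.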

How the results depend on the processing

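The fit of 13 arrays and the batch term for 3 PBS arrays were chosen after seeing the data. The cause of a change was not tested unless stated. The 5852 genes called for SP in WT and the 4775 shared by both genotypes stayed within 1.5 times under each alternative (4801 to 6146 and 4002 to 4968 with single arrays left out; 7259 with array weights; 3572 shared with the other-cell covariate). For SP in Nrf2 null, 9145 genes became 14735 with array medians centred, 4185 with the covariate, 6593 with 13 arrays and 7708 to 9334 with single arrays left out. The replicate number as a block gave 6230 (WT), 9531 (Nrf2 null), 4 (after PBS), 60 (after SP) and 1 (difference), of which 3 after PBS and 46 after SP were among the genes called without it. It ended the calls of Srxn1 and Pisd-ps3 after PBS and of Adgrb1 and Ctrl after SP, with the same differences. Among the lists, 1 lost its call after SP and 1 for the difference, while 1 gained a call after PBS. The labels pair no arrays, although 11 of 16 correlated best with an array of their own number. That is more than the share of such arrays among those compared. A shared batch stays possible, and the main fit has no term for it.

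The 5 genes after PBS became 14 with dim probe sets filtered out and 22 with all probe sets (other numbers of tests), 11 with quantile normalization, 12 with centring, 3 with no variance moderation, 3422 with array weights (0.311 to 2.21), 1 with the groups compared alone, 10 with 13 arrays, 23 with the batch term and 3 to 274 with single arrays left out. The count was 274 without Nrf2null_PBS replicate 2, 10 without Nrf2null_PBS replicate 1 and 3 without WT_PBS replicate 2, WT_SP replicate 4, Nrf2null_PBS replicate 4 or Nrf2null_SP replicate 2.

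The 60 genes after SP became 35 with no moderation, 212 with weights, 34 with the groups compared alone, 34 with the covariate, 180 with the batch term and 23 to 88 with single arrays left out (33, 29, 34 and 30 without WT_PBS replicates 1 to 4, 27, 30, 23 and 33 without WT_SP replicates 1 to 4, 39 and 31 without Nrf2null_SP replicates 2 and 3).

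The 1 gene of the difference became 3 with the dim filter, 3 with quantile normalization, 6 with centring, 4 with an intensity trend and robust prior, 0 with no moderation, 3423 with weights, 0 with the covariate, 3 with 13 arrays, 9 with the batch term and 0 to 12 with single arrays left out. It was 12 without Nrf2null_SP replicate 4, 5 without Nrf2null_PBS replicate 2 or Nrf2null_SP replicate 2, 2 without WT_PBS replicate 1 or 4 or Nrf2null_PBS replicate 1, and 0 without WT_PBS replicate 2, WT_SP replicate 1 or 4, Nrf2null_PBS replicate 4 or Nrf2null_SP replicate 1.

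Results whose change or list test took the other direction were, with the covariate, Inmt after SP in Nrf2 null (0.29), fibroblast markers after PBS (-0.377) and in the difference (0.0376), and secondary granules in the difference (-0.34). With 13 arrays they were, between genotypes after PBS, interferon gamma (-0.0502), pattern recognition receptors (0.0768), migration receptors (0.0296) and cholesterol synthesis (-0.173). The medians of other called lists took the other sign while their tests kept direction. These were, for the difference, endothelium with the covariate (0.0214), pattern recognition receptors (-0.017) and cholesterol synthesis (0.00577) with 13 arrays, and alveolar macrophages with array weights (0.193). Between genotypes after PBS they were apoptosis regulators with 13 arrays (0.0132). With centring they were oxidative phosphorylation after SP in Nrf2 null (0.0256), other antioxidant enzymes after SP (0.0256), and NRF2 targets (0.0753), other antioxidant enzymes (0.0747) and alveolar macrophages (0.0701) in the difference. Centring moved the median of all genes to 0.0907 (SP in WT), 0.391 (SP in Nrf2 null), -0.123 (after PBS), 0.143 (after SP) and 0.272 (difference). It moved the share of called genes that were higher from 48.1% to 58.3% (WT), 43.9% to 79.7% (Nrf2 null), 51.7% to 68.8% (after SP) and 0% to 83.3% (difference). Quantile normalization gave 45.5% against 20% (after PBS), 71.8% (after SP) and 66.7% (difference).

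With single arrays left out, named genes kept their side of the threshold in 1293 fits and lost a call in 3 for WT, kept it in all 1168 for Nrf2 null, kept it in 188, lost it in 16 and gained it in 4 after PBS, kept it in 278 and lost it in 74 after SP, and kept it in 164, lost it in 5 and gained it in 7 for the difference. Gene lists kept direction and side in 525 fits for WT, 551 for Nrf2 null, 507 after PBS, 515 after SP and 514 for the difference, and lost a call in 9, 2, 14, 14 and 21. With fry 2 lists lost their call for WT, none for Nrf2 null, 13 after PBS, 12 after SP and 16 for the difference. In Nrf2 null 8 lists that camera did not call were called by fry. Genes near the background of 3.61 limit what a fold can show, in rises from it as in falls to it.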

Other observations

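No test of a hypothesis in this part was chosen after its result was seen. Members of gene lists not described so far moved in both directions after SP. Which cells their RNA came from was not tested. In Nrf2null_PBS replicates 1 to 4 Ephx1 lay at 10.98, 9.84, 10.78 and 9.86, beside epithelial scores of 1.23, 0.264, 1.21 and 0.34. Among 31 NRF2 target genes in WT, 8 rose and 11 fell (9 and 12 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.737). The drug and glutathione conjugate exporter Abcc1 rose 6.93-fold and Hmox1 2.92-fold, while the epoxide hydrolase Ephx1 fell 3.15-fold and Gsta3 3.14-fold. In Nrf2 null 7 rose and 15 fell (8 and 15 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 0.124). Gsta3 fell 11.5-fold, Ephx1 6.79-fold and Gsta4 6.1-fold, while Abcc1 rose 4.69-fold. Of 7 NADPH oxidase genes in WT, the membrane subunit Cybb rose 1.79-fold and Ncf1 1.62-fold, and the list was not called (adjusted p = 0.813, and 0.429 in Nrf2 null). Of 19 glycolysis genes in WT, 3 rose and 5 fell (adjusted p = 0.277). Pfkfb3, which makes an activator of glycolysis, rose 3.35-fold and Hk2 2.44-fold, while Pfkfb4 fell 2.86-fold and the glucose transporter Slc2a3 4.05-fold. In Nrf2 null 4 rose and 8 fell (adjusted p = 0.662), with Pfkfb3 up 6.62-fold, Hk2 up 3.64-fold and Slc2a3 down 2.75-fold. Mki67, a proliferation marker, rose 4.81-fold in WT, while 8 of the other cell cycle genes fell, among them Bub1 (1.96-fold), and the list of 24 was not called (adjusted p = 0.0585). In the platelet list of Nrf2 null the collagen receptor Gp6 rose 9.46-fold and Pf4 fell 5.77-fold, and 5 of 14 members rose and 4 fell (adjusted p = 0.903).

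Further lists were not called after SP by camera, though fry called some of those in Nrf2 null. In WT the camera adjusted p was 0.985 for other antioxidant enzymes (2 of 15 rose, 4 fell), 0.948 for oxidative phosphorylation (2 of 24 rose, 2 fell), 0.419 for primary granules (1 of 9 rose), 0.985 for migration receptors (5 of 20 rose, 6 fell), 0.866 for hypoxia (5 of 18 rose, 4 fell) and 0.0763 for cholesterol synthesis (5 of 19 fell). It was 0.106 for monocytes and interstitial macrophages (6 of 17 rose, 3 fell), 0.985 for dendritic cells (2 of 15 rose, 2 fell), 0.12 for endothelium (2 of 18 fell), 0.391 for erythroid cells (2 of 9 fell), 0.804 for platelets (2 of 14 rose, 3 fell), 0.737 for mast cells, basophils and eosinophils (2 of 15 fell) and 0.785 for neutrophil precursors (2 of 17 rose, 2 fell). In Nrf2 null it was 0.171 for other antioxidant enzymes, where Sod1 fell 2.09-fold (log2 change -0.72, SE 0.315 against 0.2, adjusted p = 0.131 with the other-cell covariate), 0.166 for secondary granules, where Padi4 fell 2.48-fold and Anxa1 2.26-fold, 0.0833 for lipid mediators, 0.171 for metal handling and 0.2 for endoplasmic reticulum stress. It was 0.189 for primary granules, 0.178 for migration receptors, 0.879 for hypoxia, 0.246 for monocytes and interstitial macrophages, 0.227 for dendritic cells, 0.687 for erythroid cells, 0.687 for mast cells, basophils and eosinophils and 0.433 for neutrophil precursors. None of the 6 sex-linked genes was called by limma in the 5 contrasts.

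A hypothesis was that RNA of other cells, if it differed between the genotypes, could lower NRF2 target genes in Nrf2 null after SP. With the covariate for other cells the median of the NRF2 list was -0.725 (SE 0.154), against -0.715 without it. A shift shared by the markers of other cells is therefore not the whole source of the difference. The covariate is a mean over lists that moved in opposite directions after SP, such as epithelial markers and T and NK cell markers. It cannot stand for RNA of a single cell type, so the hypothesis stays open for RNA of epithelium or macrophages.

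Another hypothesis was that genes next to Nfe2l2 carried along with the allele may account for genotype differences outside the NRF2 list. Among the 200 genes nearest to Nfe2l2 in gene order, 1 was called in either genotype comparison, against 59 called genes in total outside the list (Fisher's exact test, one-sided, p = 0.431). After PBS 7% of these 200 genes had an unadjusted p under 0.05, against 9.11% elsewhere, so that they did not differ more often than other genes. For the 1 called gene among them, linkage cannot be told apart from an effect of NRF2, since 1 call is too few to decide. The other called genes lay outside these 200.

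A further hypothesis was that genotype differences may lie in clusters of neighbouring genes. Among the 59 called genes, 3 pairs lay within 5 positions of each other in gene order. These were Olfr1394 with Olfr1395, Ces1f with Ces1g, and Pcdhb14 with Pcdhb16, the last pair named after its values were seen. Of 10000 random sets of 59 genes, 454 had as many pairs, the median had 1 and the highest 6, so the number of pairs was above most random sets. Probe sets that cross-hybridise between related neighbours could give the same pairs and were not tested.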
